A study of Mus musculus with 4 samples.

How the data were processed

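Polyadenylated RNA of 4 libraries labelled as the mouse lung epithelial line MLE-12 was sequenced after preparation with a stranded kit, per the labels' protocols. There were 2 control libraries (replicates 1 and 2) and 2 libraries from cells kept with 5 µM 1-nitropyrene for 12 h (replicates 2 and 3). Groups and replicate numbers were taken from the sample titles. The deposited table gives raw read counts per gene, 1 column per library, with no normalization. The submitters' processing notes name HISAT2 2.1.0, featureCounts 1.6.3 and DESeq2, and the genome build GRCm38 (mm10), without their roles. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads of near-identical genes, of pseudogenes and of genes that overlap on opposite strands can therefore be assigned to the wrong gene or to both.

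The table held 53465 gene identifiers, of which 53360 were matched to GENCODE M21 on GRCm38 for symbols, gene types and coordinates. The 105 unmatched identifiers held between 26 and 37 counts per library and were kept under their identifiers. Total counts per library ranged from 6908055 to 10773733, so that 3 counts, used as the floor for a count of 0, correspond to 0.278 to 0.434 CPM. Intervals are at the 95% level.

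Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr on the group, which left 7738 genes (6738 protein-coding, 560 pseudogenes), and library sizes were scaled with TMM factors between 0.989 and 1.01. The model held an intercept and the treatment. The quasi-likelihood fit used the method of edgeR 4 (legacy set to FALSE, since this version's function defaults to the older method), with an estimated dispersion of 0.000546, a biological coefficient of variation of 2.34%. Its prior degrees of freedom were infinite, so all genes shared 1 spread. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All tests are two-sided.

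Replicates were compared with a chi-square test of counts over genes with at least 10 counts. The statistic per degree of freedom was 1.62 between the controls and 2.05 between the treated libraries, above sampling noise, and 9.43 between control replicate 2 and 1-nitropyrene replicate 2. No 2 libraries were counted as 1 sample.

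Gene lists were tested with camera at a preset correlation of 0.01 over the 27 lists with at least 5 tested members, with Benjamini-Hochberg adjustment. Fry was run as an alternative: its directional p asks whether the genes of a list move, on balance, one way and does not compare a list with other genes. The 34 lists cover m6A and SUMO enzymes, SCF-Fbxw7 and substrates, targets of the Ah receptor, Nrf2, p53, ATF4, NF-kB, TGF-beta and YAP, interferon, senescence and its secreted factors, telomeres, DNA repair, cell cycle (G1/S and G2/M), endoplasmic reticulum and heat shock chaperones, matrix, epithelial, alveolar, airway and other cell markers, mitochondrial genes of 3 kinds, cholesterol and fatty acid synthesis, immediate early genes, hypoxia and glycolysis, autophagy, ribosomal proteins and histones. Named genes are Fbxw7 and Alkbh5, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and both treated libraries on the same side of both controls (predicted genes, RIKEN clones, pseudogenes and mitochondrial rRNA and tRNA left out), up to 4 members of each list with the smallest p, and Cyp1a1, Cyp1b1, Hmox1, Nqo1, Cdkn1a, Mdm2, Lmnb1, Sftpc, Cdh1 and Fn1. Reference genes in the description of the libraries (Krt8, Krt18, Krt19, Sftpb, Nkx2-1, Actb), Acta2, the untested matrix genes, Gnas, Gm20721 and Lars2 were chosen after their values were seen. The test, the lists, the rule for named genes and 16 of the 21 alternative settings were fixed before the data were examined.

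The alternatives were other scaling factors (RLE, upper quartile, none), other filters on low counts, DESeq2 1.42.0, limma-voom, the older quasi-likelihood method, a stricter adjusted p of 0.01, a fold of at least 2, an estimated correlation and fry for the lists, and each library left out in turn. With 1 library left out, the lone library of a group is assumed to vary like the pair in the other group. Added after seeing the data were a robust quasi-likelihood fit, a fit without rRNA loci, a mean of at least 10 CPM, a test against a 1.2-fold change and protein-coding genes only.

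The fit was tested on simulated data: negative binomial counts for the 7738 genes of the comparison of 1-nitropyrene with control, at a dispersion of 0.001, with 200 changed genes. It recovered 44.8% of genes changed 1.25-fold, 68.7% changed 1.5-fold and 87.9% changed 2-fold. Of the called genes 2.9% were unchanged ones, and 0 recovered genes had the wrong sign. The simulation gave all genes 1 spread and does not cover genes with a wider one.

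Transcripts of Lars2 were searched with BLAST 2.17.0 (blastn, word size 7) against mt-Rnr2, Gm42418 and CT010467.1, and thinning of counts to 50% was done with numpy 2.4.6 in Python 3.11.15. Median GC content was 49.1% in the higher, 51.2% in the lower and 49.1% in the uncalled genes. The median of mean CPM was 71.2, 38.6 and 11.3 in the same order. Across genes, which are not independent replicates, Spearman's rho of the log2 fold change was -0.07 with GC content and -0.07 with transcript length. It was 0.14 with mean CPM. Whether abundance had a part in the list calls was not tested.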

Results

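The effect of 1-nitropyrene, a nitrated polycyclic hydrocarbon found in diesel exhaust, was examined by sequencing of polyadenylated RNA from libraries labelled as MLE-12, an immortalized mouse lung epithelial line with features of alveolar type 2 cells. Cells were labelled as control (n = 2 libraries) or received 5 µM 1-nitropyrene for 12 h (n = 2 libraries). The table of raw counts per gene held 10773733 and 6908055 counts in control replicates 1 and 2, and 8797502 and 8601825 counts in 1-nitropyrene replicates 2 and 3. Values below, unless stated as CPM of total counts, are TMM-normalised CPM (counts scaled to a common library size), given as mean ± SD with n = 2 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood test over 7738 genes. The labels did not say that the libraries came from separate cultures, so the spread between the libraries may be technical. These p-values measured only that spread, pooled over all genes. They, and the standard errors, took no account of how far a single gene's own replicates differed. Gene names are those of the mouse loci to which the counts were assigned.

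The transcript profile, given here in CPM of total counts without TMM factors, held few of the genes that mark lung epithelium. Keratins Krt8, Krt18 and Krt19, the junction protein E-cadherin (Cdh1), the surfactant gene Sftpb and the lung transcription factor Nkx2-1 had 0 counts in all 4 libraries, and the surfactant gene Sftpc had 1 count in 1 library. A count of 0 allowed up to 0.434 CPM in the shallowest library, at a floor of 3 counts. Between 36.7% and 40.6% of the 21942 annotated protein-coding genes had a count, and 12111 (55.2%) had none in any library. Loci of ribosomal RNA took 46.1% and 45.8% of the counts in the control libraries and 44.5% and 44.3% in the treated libraries. The 13 mitochondrially encoded mRNAs together reached 46.9 and 30.4 CPM in control replicates 1 and 2, 24.6 CPM in 1-nitropyrene replicate 2 and 1.86 CPM in 1-nitropyrene replicate 3. The 2 mitochondrial rRNAs reached 1730 and 1720 CPM in the controls and 1260 and 1310 CPM in the treated libraries. Cytosolic ribosomal protein genes had median counts of 11, 6, 5 and 8 in the same order, while Actb (actin) had 11000, 11100, 12900 and 12900 CPM.

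**Figure D1:**
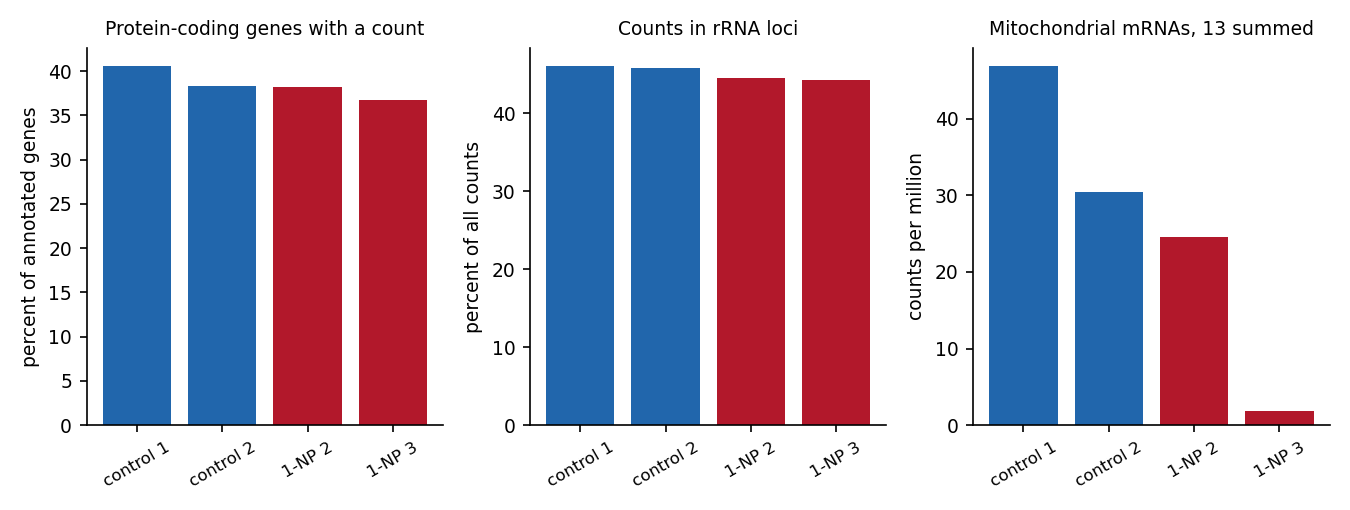
Bars give 1 value per library (blue, control; red, 1-nitropyrene) for the percent of annotated protein-coding genes with at least 1 count, the percent of all counts in rRNA loci, and the summed CPM of total counts of the 13 mitochondrial mRNAs. The first measure lay between 36.7% and 40.6%, and the mitochondrial mRNAs between 1.86 and 46.9 CPM.

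The main comparison asked which transcripts changed with 1-nitropyrene. Fibronectin (Fn1), a matrix glycoprotein, the receptor tyrosine kinase Axl and the matricellular protein Ccn1 rose about 2-fold, as did Insig1, which restrains sterol synthesis. The immediate early transcription factor Egr1, the NF-kB inhibitor Nfkbia and the mTORC1 inhibitor Ddit4 fell by more than 2-fold. Of the measured list members, 6 of 12 heat shock response genes and 7 of 17 hypoxia and glycolysis genes rose (0 and 1 fell), and 10 of 17 targets of the stress-induced transcription factor ATF4 fell. These 3 list calls were not kept by camera in edgeR with an estimated correlation (adjusted p = 0.49 with an estimated correlation). Transcripts of Fbxw7, named in the study's stated purpose, and of Alkbh5, named in its title, did not pass the test.

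Fbxw7 encodes the substrate-binding subunit of an SCF ubiquitin ligase, and the study's stated purpose was the influence of 1-nitropyrene on translation of its mRNA. The counts measured its RNA level only. Fbxw7 (GRCm38 chromosome 3, 84815268 to 84979198) was at 28.3 ± 1.59 CPM in control and 24.2 ± 1.19 CPM with 1-nitropyrene, a log2 fold change of -0.21 (SE 0.12, adjusted p = 0.196, edgeR). Both treated libraries (23.3 and 25 CPM) lay below both controls (27.1 and 29.4 CPM), and the 95% interval of the treated-to-control ratio was 0.733 to 1.02. Alkbh5 (chromosome 11, 60536381 to 60558512) encodes an RNA demethylase that removes N6-methyladenosine (m6A). It was at 41.4 ± 4.29 CPM in control and 38.8 ± 6.81 CPM with 1-nitropyrene, a log2 fold change of -0.07 (SE 0.10, adjusted p = 0.641, edgeR). The 2 groups overlapped, and the 95% interval of the ratio was 0.833 to 1.08. Its direction depended on single libraries, at 0.01 without control replicate 2, 0.10 without 1-nitropyrene replicate 3 and -0.26 without 1-nitropyrene replicate 2.

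**Figure D2:**
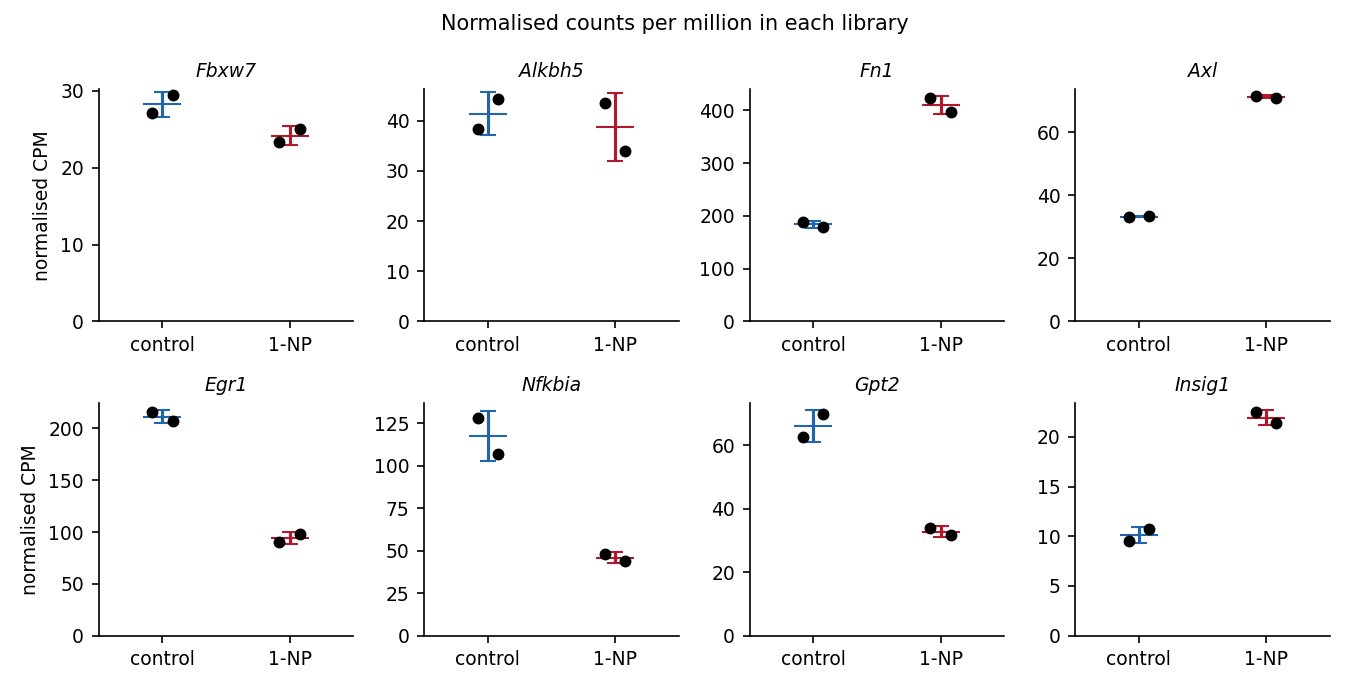
Points are TMM-normalised CPM of single libraries (2 per group, 1-NP for 1-nitropyrene), with the group mean as a horizontal bar and the SD as error bars, on axes that start at 0. Fn1, Axl and Insig1 were higher and Egr1, Nfkbia and Gpt2 lower in both treated libraries than in both controls, whereas the libraries of Alkbh5 overlapped.

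Across the transcriptome 1024 genes were higher and 870 lower with 1-nitropyrene, together 24.5% of those tested. The median called gene changed 1.29-fold. Changes of at least 2-fold numbered 57 higher and 102 lower, and 136 of these 159 genes had a mean below 10 CPM. In 1876 of the 1894 called genes both treated libraries lay on the same side of both controls. The call from these same libraries favours this, so it is no separate support. DESeq2 called 448 higher and 249 lower genes, and without control replicate 1 edgeR called 690 higher and 511 lower. Of the called genes 647 (34.2%) shared exon sequence with a gene on the opposite strand, and the strand setting of the authors' counting was not given in the sources used here, so their counts may include reads of the partner. Gnas and its opposite-strand partner Gm20721 had nearly equal counts, 69198 and 66203 in control replicate 1.

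**Figure D3:**
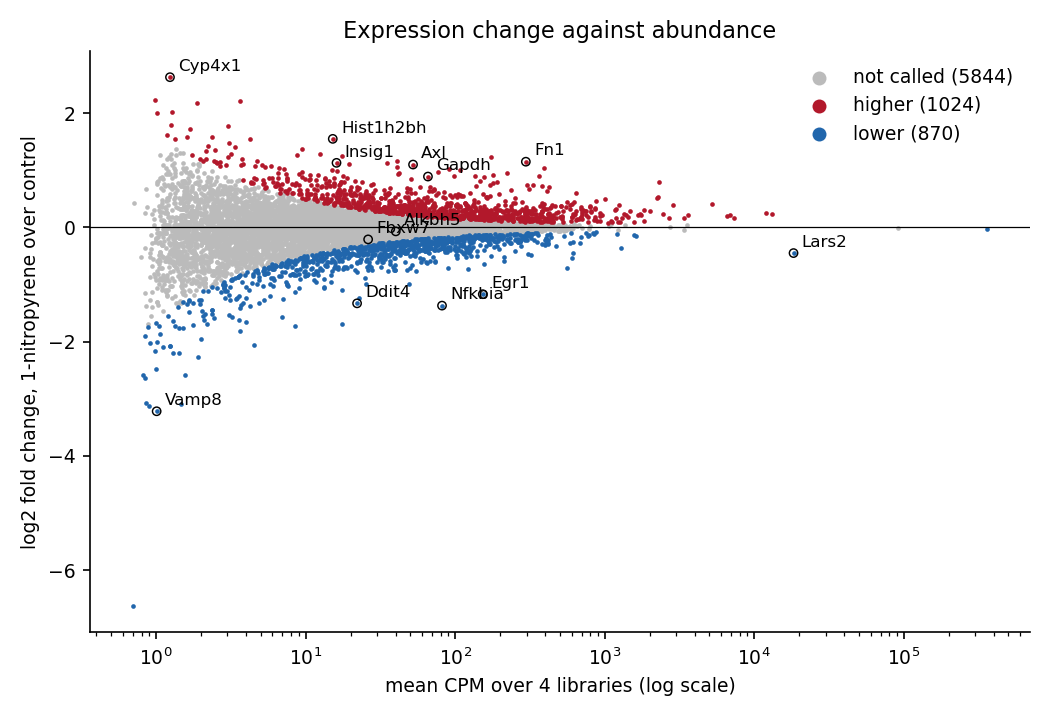
Each point is 1 of the 7738 tested genes, with its mean CPM on a log axis and its log2 fold change (1-nitropyrene over control). Red and blue points are the 1024 higher and 870 lower genes, grey points did not pass the test, and circles mark named genes.

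The steepest rises were at low counts. Cyp4x1, a cytochrome P450, rose from 0.327 ± 0.0575 to 2.16 ± 0.608 CPM (log2 fold change 2.63, SE 0.65), and the tumour suppressor candidate Tusc2 from 0.655 ± 0.115 to 3.08 ± 0.364 CPM (2.17, SE 0.51). Both share exon sequence with an opposite-strand gene (450 and 484 bp). Wnt2, a secreted Wnt ligand, Adprhl2, an ADP-ribose hydrolase, Zfp105, a zinc finger protein, and the chemokine scavenger receptor Ackr3 rose by log2 fold changes between 1.78 and 2.02. Fam107b, Aff2 and Dtwd2 rose by 1.54 to 1.61. The histone gene Hist1h2bh rose from 7.70 ± 0.555 to 22.8 ± 0.348 CPM (1.55, SE 0.17, adjusted p = 1.85e-18), with reads that near-identical histone genes could share.

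The steepest falls were at low counts too. Vamp8, a vesicle fusion protein, had 31 counts in the controls and 3 in the treated libraries, a ratio of 9.96 with a 95% counting interval of 3.11 to 50.9. The matrix protein Spon2 had 46 and 5 counts, and the focal adhesion scaffold Pxn (paxillin) 45 and 7. Other genes that fell by at least 2.08 on the log2 scale were the RNA polymerase III subunit gene Polr3gl, the podosome scaffold Sh3pxd2b, the chromatin-associated protein Trnp1, the focal adhesion protein Parvb, the actin-capping Tmod2, the ubiquitin ligase component Asb7 and mitochondrial mt-Nd4. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Of these 20 steepest genes, 14 lost their call in edgeR when 1 of the 4 libraries was left out, and Cyp4x1, Tusc2, Hist1h2bh, Dtwd2, Vamp8 and Spon2 kept it. DESeq2 gave no adjusted p for 19 of the 20 and called only Hist1h2bh.

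Of 34 gene lists 27 had at least 5 measured members, and edgeR's camera test with a preset correlation of 0.01 placed 4 higher and 4 lower with 1-nitropyrene. With an estimated correlation, a setting that leaves only the residual degrees of freedom of 4 libraries, camera called 0 higher and 0 lower. With 1 list at an unadjusted p under 0.05 (0.0296), all 8 calls were lost. The estimated correlation lay below 0.01 for the ATF4 (-0.0244), NF-kB (-0.0567), hypoxia (-0.0249) and cholesterol (-0.136) lists. Their lost calls therefore do not show correlated members. It was 0.0905 to 0.0917 for the heat shock, immediate early and TGF-beta lists and 0.953 for the mitochondrially encoded list. Targets of ATF4 in the integrated stress response, which raises amino acid supply, had 10 of 17 measured members lower and 0 higher (camera adjusted p = 3.62e-06). The counts were the same when adjusted over the list alone. This list names 31 genes, and 8 of them had 0 counts in all 4 libraries, among them Ddit3, Trib3 and Atf3. Asns had 3 counts in total and was not tested. The alanine aminotransferase Gpt2 fell from 66.1 ± 5.03 to 32.8 ± 1.72 CPM (log2 fold change -1, SE 0.09, adjusted p = 1.9e-26). Ddit4 fell from 31.7 ± 0.985 to 12.6 ± 1.18 CPM (-1.33, SE 0.14), the transcription factor Cebpb from 286 ± 17.3 to 215 ± 0.74 CPM (-0.42, SE 0.04), and the lipoprotein receptor Vldlr from 151 ± 6.91 to 106 ± 8.61 CPM (-0.50, SE 0.06). With an estimated correlation the list was not called (adjusted p = 0.49 with an estimated correlation).

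Immediate early and AP-1 genes, which respond within minutes to growth factors and stress, were lower as a list (adjusted p = 0.00134 with the preset correlation, adjusted p = 0.49 with an estimated correlation) but moved both ways, and fry did not call the list (adjusted p = 0.0573). Of 14 measured members 5 fell and 3 rose, the same counts when adjusted over the list alone. Egr1 fell from 211 ± 6.21 to 94 ± 5.63 CPM (log2 fold change -1.17, SE 0.05, adjusted p = 1.7e-101), Klf6 from 152 ± 0.696 to 91.4 ± 4.03 CPM (-0.73, SE 0.06) and Junb from 121 ± 5.1 to 85.6 ± 2.56 CPM (-0.49, SE 0.06), while Jund rose from 380 ± 16.5 to 482 ± 17.6 CPM (0.34, SE 0.04). Egr1 lies on chromosome 18 (34859823 to 34864984).

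The list of NF-kB inflammatory targets was lower (camera adjusted p = 0.000865, adjusted p = 0.49 with an estimated correlation). Of its 28 members 7 were measured, with 2 lower, or 3 when adjusted over the list alone. Another 14 had 0 counts in all 4 libraries, among them the cytokines Il6, Il1b and Tnf and the chemokines Cxcl1 and Ccl2. Nfkbia, which encodes the inhibitor that retains NF-kB in the cytoplasm, fell from 118 ± 14.8 to 46 ± 3.16 CPM (log2 fold change -1.37, SE 0.07, adjusted p = 4.16e-78). Nfkb2, a subunit of NF-kB itself, fell from 23.2 ± 1.29 to 16.1 ± 1.56 CPM (-0.52, SE 0.14, adjusted p = 0.00168, edgeR), a call that ended in DESeq2 (adjusted p = 0.11) and without 1-nitropyrene replicate 2 (adjusted p = 0.0595).

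All 7 measured mitochondrially encoded mRNAs, subunits of the respiratory chain, were lower, also when adjusted over the list alone (adjusted p = 3.02e-05, adjusted p = 0.493 with an estimated correlation). Fry did not call this list (adjusted p = 0.26). The cytochrome oxidase subunit mt-Co1 had 176 and 67 counts in the controls and 67 and 3 in the treated libraries. The fit gave every gene the same spread, and a robust fit that allowed wider spreads kept 4 of the 7 calls, losing mt-Co1 (adjusted p = 0.475), mt-Cytb (0.332) and mt-Nd1 (0.0676). Without 1-nitropyrene replicate 3, the library with 1.86 CPM of total counts in mitochondrial mRNA, the list had a median log2 fold change of -0.65 and was not called (adjusted p = 0.11).

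Among the lists that were higher, the cytosolic heat shock response had 6 of 12 measured members higher and 0 lower, the same counts when adjusted over the list alone (adjusted p = 0.00303, adjusted p = 0.49 with an estimated correlation). The constitutive chaperone Hspa8 rose from 447 ± 19.5 to 582 ± 0.744 CPM (log2 fold change 0.38, SE 0.03), Hsp90aa1 from 442 ± 8.85 to 574 ± 2.1 CPM (0.38, SE 0.03) and Hsp90ab1 from 579 ± 8.48 to 678 ± 5.33 CPM (0.23, SE 0.03). Hsf1, the transcription factor that drives this response, rose by 0.17 (SE 0.04). The members Hspa1a and Hspa1b had 6 and 5 counts in total over the 4 libraries and were not tested.

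Hypoxia and glycolysis genes were higher (adjusted p = 0.0046, adjusted p = 0.49 with an estimated correlation), with 7 of 17 measured members higher and 1 lower, the same counts when adjusted over the list alone. The glucose transporter Slc2a1 rose from 164 ± 3.31 to 206 ± 4.82 CPM (log2 fold change 0.34, SE 0.05), and the glycolytic enzymes Pkm from 307 ± 1.15 to 382 ± 5.93 CPM (0.31, SE 0.04) and Aldoa from 1290 ± 22.2 to 1500 ± 6.52 CPM (0.22, SE 0.03). Gapdh rose from 46 ± 2.38 to 85.6 ± 1.39 CPM (0.89, SE 0.08), with many pseudogene copies that could share its reads.

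Targets of TGF-beta and YAP, regulators of matrix production and growth, were higher (adjusted p = 0.00158, adjusted p = 0.49 with an estimated correlation), with 5 of 13 measured members higher and 1 lower, the same counts when adjusted over the list alone. Axl rose from 33.3 ± 0.133 to 71.3 ± 0.474 CPM (log2 fold change 1.10, SE 0.09, adjusted p = 7.17e-34) and Ccn1 from 26.5 ± 0.48 to 54.7 ± 3.88 CPM (1.05, SE 0.10). The inhibitors of differentiation moved apart, Id3 rising by 0.28 (SE 0.04) and Id2 falling from 79 ± 2.59 to 51.2 ± 3.33 CPM (-0.62, SE 0.08).

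Cholesterol synthesis and uptake genes were higher (adjusted p = 0.0133, adjusted p = 0.49 with an estimated correlation), with 3 of 8 measured members higher and 0 lower, or 4 higher when adjusted over the list alone. The list names 25 genes, and 9 of them had 0 counts in all 4 libraries. Insig1 rose from 10.2 ± 0.837 to 22 ± 0.816 CPM (log2 fold change 1.13, SE 0.16, adjusted p = 4.18e-11). The isomerase Idi1 rose by 0.50 (SE 0.13), a call that ended in DESeq2 (adjusted p = 0.0793). The list itself was not called without a filter on low counts (adjusted p = 0.16) or at a mean of at least 10 CPM (adjusted p = 0.079).

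**Figure D4:**
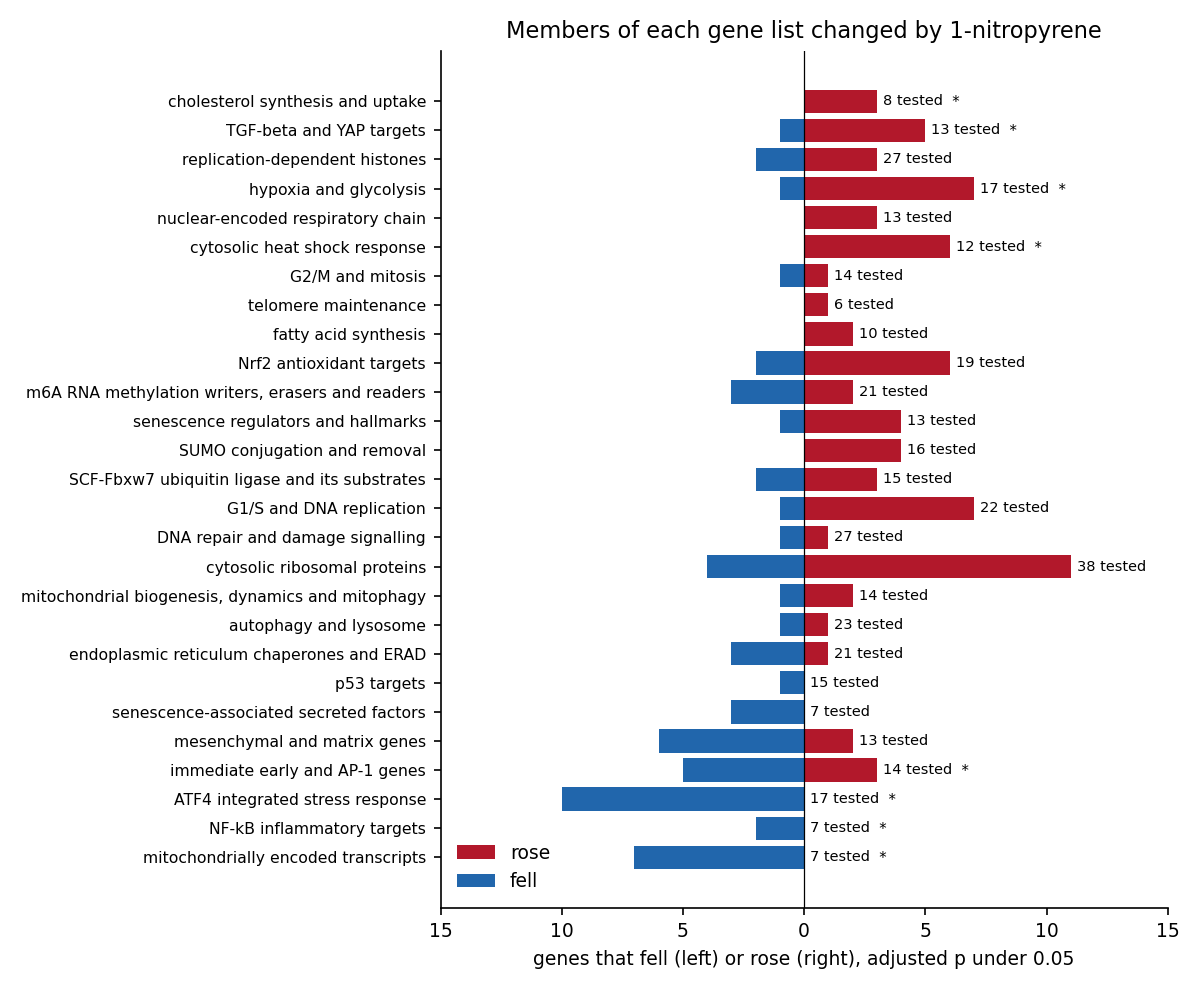
Bars count the members of each list that rose (red, right) or fell (blue, left) at an adjusted p under 0.05 in edgeR, for the 27 lists with at least 5 tested members, ordered by median log2 fold change. Stars mark the 4 higher and 4 lower lists called with a preset correlation.

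Mesenchymal and matrix genes moved both ways and were not called as a list (camera adjusted p = 0.689, fry adjusted p = 0.122). Of 13 measured members 2 rose and 6 fell, or 2 and 7 when adjusted over the list alone. The median log2 fold change was -0.19 and the mean -0.17, while camera put the list on the higher side. Fn1 (chromosome 1, 71585520 to 71653200) rose from 184 ± 6.84 to 410 ± 17.6 CPM (log2 fold change 1.15, SE 0.04, adjusted p = 2.35e-164), with 292 bp of exon shared with an opposite-strand gene. The intermediate filament gene Vim rose from 337 ± 0.609 to 396 ± 11 CPM (0.23, SE 0.04). Collagen gene Col5a1 fell from 83.3 ± 4.09 to 63.6 ± 0.426 CPM (-0.40, SE 0.07) and Sparc, a collagen-binding glycoprotein, from 434 ± 11.7 to 381 ± 3.26 CPM (-0.19, SE 0.04). Smooth muscle actin Acta2 had 36 and 7 counts in the controls and 12 and 0 in the treated libraries, lowest in 1-nitropyrene replicate 3, as were the mitochondrial mRNAs. Of the members below the filter, which were not tested, Col1a1 had 9 and 5 counts in the controls and 0 and 2 in the treated libraries, Col1a2 17 and 7 against 0 and 1, Col3a1 13 and 3 against 2 and 0, Tagln 10 and 7 against 1 and 0, and Postn 6 and 3 against 0 and 0. Thbs1 had 9 and 5 against 10 and 9, and Snai1 8 and 2 against 6 and 2.

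Lists built around the study's subject were not called by camera, and fry called 1 of them. Among m6A writers, erasers and readers, 2 of 21 measured members rose and 3 fell (adjusted p = 0.937), with the adaptor Rbm15 falling from 53 ± 1.23 to 38.9 ± 0.721 CPM (log2 fold change -0.44, SE 0.09) and the reader Hnrnpa2b1 from 1640 ± 12.4 to 1490 ± 20.3 CPM (-0.14, SE 0.02). In the SUMO conjugation and removal list 4 of 16 members rose and 0 fell (camera adjusted p = 0.168, fry adjusted p = 0.0117), among them the modifier Sumo2, from 848 ± 6.91 to 1020 ± 8.79 CPM (0.26, SE 0.03). Of the 4, Uba2 lost its call in DESeq2 (adjusted p = 0.275), without a filter on low counts (adjusted p = 0.0573) and whichever library was left out (adjusted p = 0.0817 to 0.156, edgeR), and Ranbp2 in DESeq2 (adjusted p = 0.112) and without 1-nitropyrene replicate 3 (adjusted p = 0.0505). Within the list of SCF-Fbxw7 and its substrates 3 of 15 rose and 2 fell (adjusted p = 0.583, median log2 fold change 0.05, camera direction lower), and the transcription factor Nfe2l1 fell from 693 ± 22.4 to 421 ± 7.23 CPM (-0.72, SE 0.03). These 3 lists had the same counts when adjusted over the list alone.

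Senescence regulators and hallmarks had 4 of 13 members higher and 1 lower, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.586, fry higher at 0.0302). The deacetylase Sirt1 rose from 15.5 ± 0.98 to 24.1 ± 0.0384 CPM (log2 fold change 0.65, SE 0.14) and the cell cycle inhibitor Cdkn1b from 16.8 ± 1.21 to 25.2 ± 0.849 CPM (0.60, SE 0.14). Lamin B1 (Lmnb1), whose loss marks senescence, was at 44.5 ± 0.526 CPM in control and 40.6 ± 3.91 CPM with 1-nitropyrene (-0.14, SE 0.09, adjusted p = 0.315, edgeR). The p53 target Cdkn1a had 0 counts in all 4 libraries, and Mdm2 had 1 and 2 counts in the controls and 0 in both treated libraries. Of 45 secreted factors of senescence only 7 were measured, and 24 had 0 counts in all 4 libraries, among them Il6, Il1b, Cxcl1 and Ccl2. Of the measured ones 3 were lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 0.118, fry lower at 0.00189). The lower ones included the macrophage growth factor Csf1, from 10 ± 1.2 to 4.14 ± 1.13 CPM (-1.25, SE 0.24), and the protease inhibitor Timp2, from 138 ± 0.142 to 110 ± 6.21 CPM (-0.33, SE 0.06). In the p53 list of 30 genes, 10 had 0 counts in all 4 libraries. Of its 15 measured members 1 fell, Ei24 (-0.37, SE 0.07), and 0 rose, the same counts when adjusted over the list alone (camera adjusted p = 0.479).

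Nrf2 antioxidant targets had 6 of 19 members higher and 2 lower, or 8 and 2 when adjusted over the list alone (camera adjusted p = 0.109, fry higher at 0.0117). Ferritin heavy chain (Fth1) rose from 1830 ± 40 to 2620 ± 4.66 CPM (log2 fold change 0.52, SE 0.02) and heme oxygenase (Hmox1) from 1.75 ± 0.649 to 4.95 ± 0.815 CPM (1.41, SE 0.35, adjusted p = 0.000582, edgeR). The Ah receptor targets Cyp1a1 and Cyp1b1, which metabolise polycyclic hydrocarbons, had 1 count each over all 4 libraries, and Nqo1 had 0, so no fold change could be given for these genes. Only 3 members of the Ah receptor list were measured, and 1 rose, Tiparp, by 0.23 (SE 0.06), also when adjusted over the list alone, a call that ended in DESeq2 (adjusted p = 0.0724).

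Proliferation genes rose in part without a list call by camera, while fry called the first of these lists higher (adjusted p = 0.0167). In the G1/S and DNA replication list 7 of 22 members rose and 1 fell, the same counts when adjusted over the list alone (adjusted p = 0.315), with the sliding clamp Pcna rising from 27.9 ± 1.7 to 45.4 ± 3.49 CPM (log2 fold change 0.69, SE 0.10) and the helicase subunit Mcm6 from 189 ± 1.94 to 227 ± 4.94 CPM (0.27, SE 0.05). Of 31 G2/M and mitosis genes 14 were measured, and 12 had 0 counts in all 4 libraries. Among the measured ones 1 rose (Top2a) and 1 fell (Ccna2), or 0 and 1 when adjusted over the list alone (camera adjusted p = 0.762). Both calls ended in DESeq2 (adjusted p = 0.405 and 0.256) and without a filter on low counts (0.128 and 0.0743, edgeR). The DNA repair list had 1 of 27 higher and 1 lower, the same counts when adjusted over the list alone (adjusted p = 0.862). In the telomere list 1 of 6 rose, the telomerase component Dkc1 (0.33, SE 0.04), or 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.586, mean log2 fold change -0.01, camera direction higher). Replication-dependent histones had 3 of 27 higher and 2 lower, the same counts when adjusted over the list alone (adjusted p = 0.479).

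In the endoplasmic reticulum chaperone list 1 of 21 members rose and 3 fell (adjusted p = 0.408), with the disulfide isomerases moving apart: Pdia4 fell from 125 ± 10.2 to 93.5 ± 5.56 CPM (log2 fold change -0.41, SE 0.06) and Pdia3 rose from 384 ± 17.6 to 452 ± 4.1 CPM (0.24, SE 0.04). Nuclear-encoded respiratory chain genes had 3 of 13 higher and 0 lower (camera adjusted p = 0.336, fry higher at 0.033), among them cytochrome c (Cycs, 0.16, SE 0.04). Cytosolic ribosomal protein genes had 11 of 38 higher and 4 lower, or 11 and 5 when adjusted over the list alone (adjusted p = 0.117, mean -0.01, camera direction higher), with Rps19 rising by 0.54 (SE 0.05) and pseudogene copies that could share their reads. In the mitochondrial biogenesis list 2 of 14 rose and 1 fell, the coactivator Ppargc1a (-0.66, SE 0.10), or 2 and 3 when adjusted over the list alone (adjusted p = 0.586). Fatty acid synthesis genes had 2 of 10 higher and 0 lower, or 3 and 0 when adjusted over the list alone (camera adjusted p = 0.367, fry higher at 0.0371), including the citrate lyase Acly (0.32, SE 0.04). The autophagy and lysosome list had 1 of 23 higher and 1 lower (adjusted p = 0.762). The chaperone, respiratory chain and autophagy lists had the same counts when adjusted over the list alone.

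Markers of lung cell types were too sparse for a list test. Of 20 epithelial junction and keratin genes 2 were measured, the junction scaffold Tjp1, which rose by 0.28 (SE 0.05), and the integrin Itgb4, which fell from 20.4 ± 0.28 to 12.3 ± 0.141 CPM (log2 fold change -0.73, SE 0.15). Of 20 alveolar type 2 markers 4 were measured and 0 passed the test in edgeR, also when adjusted over the list alone. Of 15 alveolar type 1 and transitional markers only Cav1 was measured, falling from 88.9 ± 6.09 to 58.7 ± 4.69 CPM (-0.61, SE 0.07). Of 18 markers of fibroblasts, endothelium and leukocytes only Pdgfra was measured (1.63 ± 0.685 and 0.755 ± 0.0707 CPM, adjusted p = 0.118, edgeR), and it was not called. Its unadjusted p was 0.037 (edgeR), which adjustment over a list with 1 tested member leaves unchanged. Of 14 airway markers and 27 interferon-stimulated genes 0 passed the filter on low counts.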

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

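The robust fit, the fit without rRNA loci, the mean of at least 10 CPM, the test against a 1.2-fold change and the fit of protein-coding genes only were chosen after the result was seen. No paired analysis was possible because the groups share only 1 replicate number. Against 1024 higher and 870 lower genes, DESeq2 called 448 and 249, all 697 of them among the 1894, and the cause was not tested. A fold of at least 2 left 57 and 102 by its own construction, and a test against a 1.2-fold change left 239 and 214. An adjusted p under 0.01 left 568 lower genes. Without a filter on low counts 532 were lower, and the cause was not tested. Leaving out 1 library gave 690 to 861 higher and 511 to 647 lower genes, lowest without control replicate 1, with fewer samples in each fit. Those fits shared 60.2% to 72.1% of the calls, and no shared call changed sign in any setting. Scaling moved the median log2 fold change of all genes by at most 0.03, and with library size only 868 genes were higher and 1017 lower (46.0% of calls higher, against 54.1%). For the lists, with 4 higher and 4 lower, camera with an estimated correlation called 0 and 0 (1 list at an unadjusted p under 0.05). That setting leaves only the residual degrees of freedom of 4 libraries, and the share of this in the loss was not tested. A mean of at least 10 CPM left 2 lower, since the NF-kB and mitochondrially encoded lists then had fewer than 5 members and were not tested. Fry, which asks another question, called 10 higher and 3 lower: the immediate early (adjusted p = 0.0573) and mitochondrially encoded (0.26) lists were no longer called and the secreted factors of senescence (0.00189) were, and the 6 added higher lists were SUMO conjugation and removal (0.0117), Nrf2 targets (0.0117), G1/S and DNA replication (0.0167), senescence regulators (0.0302), the nuclear-encoded respiratory chain (0.033) and fatty acid synthesis (0.0371). Leaving out 1 library gave 4 to 5 higher and 3 to 4 lower lists. Fbxw7 ranged from -0.28 to -0.16 and Alkbh5 from -0.26 to 0.10 on the log2 scale over the fits without 1 library, and neither passed the threshold in any setting. Alkbh5 was above 0 without control replicate 2 (0.01) and without 1-nitropyrene replicate 3 (0.10). Of 109 called named genes, 71 kept their call whichever library was left out, and 23 of the 86 called named genes with an adjusted p in DESeq2 lost their call there. No called gene or list reversed in any setting run. Genes with a mean below 10 CPM, where counts were low, held 136 of the 159 changes of at least 2-fold, and the effect of depth on their calls was not tested.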

Other observations

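The tests of mitochondrial mRNA as a sign of another mammal and of 1-nitropyrene as the whole cause of the mitochondrial pattern were chosen after the result was seen, as was the selection of genes in the next paragraph.

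Among genes with a mean of at least 10 CPM, 14 rose and 9 fell by at least 2-fold with 1-nitropyrene, and 11 and 8 of these were protein-coding. Beside those described above, the neuropeptide precursor Vgf rose from 6.93 ± 2.3 to 17.8 ± 3.92 CPM, the fibrillar collagen Col5a2 from 10.3 ± 0.244 to 24.5 ± 2.76 CPM and the small calpain subunit Capns1 from 25.5 ± 1.85 to 56.7 ± 6.86 CPM (n = 2 libraries per group). The ATPase Ola1 rose from 256 ± 1.55 to 526 ± 17.7 CPM and the splicing factor Wbp11 from 59.8 ± 0.548 to 121 ± 0.0453 CPM. On the lower side were the mesenchymal transcription factor Prrx1, from 31.9 ± 2.15 to 13.4 ± 1.44 CPM, the basement membrane collagen Col4a5, from 23.7 ± 1.32 to 11.2 ± 1.24 CPM, and the kinase ERK1 (Mapk3), from 34 ± 2.43 to 17.1 ± 0.397 CPM. All 8 passed edgeR's test, with adjusted p between 2.35e-164 for Ola1 and 3.93e-11 for Vgf. The pseudogene Gm5801 was called lower although its control libraries held 467 and 61 counts and its treated libraries 75 and 80.

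Few protein-coding genes carried counts. Actb had at least 11000 CPM of total counts in each library, but several other mRNAs that every cell uses were near 0. Sequencing too shallow to see them is argued against, since thinning each library to 50% lowered the number of protein-coding genes with a count by a median of 5.46%, and counting on the opposite strand is argued against, since at most 32.1% of protein-coding counts lay in genes that share exon sequence with an opposite-strand gene (the near-equal counts of Gnas and Gm20721 leave counting on both strands open). A candidate explanation is that most reads came from another mammal and that mainly conserved sequence aligned to the mouse genome. The 13 mitochondrial mRNAs, which diverge quickly between species, reached at most 0.00869% of the counts outside rRNA loci although both mitochondrial rRNAs were present, and the fast-evolving mouse genes H2-K1, H2-D1 and B2m together reached at most 0.682 CPM of total counts, both of which that explanation needs. A search of the reads against other genomes was not done here, and no biological explanation was tested.

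The mitochondrial mRNAs were lower with 1-nitropyrene. An effect of 1-nitropyrene as the whole cause cannot be told apart from a difference between libraries: the treated libraries lay 22.7 CPM of total counts apart and the group means 25.4 CPM, a gap of -2.74 CPM with a counting SE of 2.92 that leaves out the spread between libraries. The difference was the first criterion and was not exceeded, it was replaced by the ratio after the values were seen and then restored, and the limit from the counting SE was also set after. As a ratio the treated libraries differed 13.2-fold (95% counting interval 7.94 to 23.5) and the group means 2.92-fold, while control replicate 2 exceeded 1-nitropyrene replicate 2 by 1.24-fold (1.02 to 1.5). A small mouse RNA fraction that varies between libraries may contribute and stays open too, because H2-K1, H2-D1 and B2m had 17 counts in all, with 1-nitropyrene replicate 3 at 1.2 times the lowest library (0.138 to 14.4).

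Lars2, the mitochondrial leucyl-tRNA synthetase, held more counts than any other protein-coding gene and fell from 21100 ± 153 to 15500 ± 127 CPM (log2 fold change -0.45, SE 0.01). Reads of the mitochondrial 16S rRNA assigned to it are argued against, since the longest match of a Lars2 transcript to mt-Rnr2 at 80% identity or more was 30 bp. Reads of the cytosolic rRNA sequence at Gm42418 and CT010467.1 are argued against as well. Lars2 and Gm42418 differed by 0.43 in log2 fold change, and the longest match to either locus was 29 bp. Those loci overlap, and cytosolic rRNA sequence outside them was not searched. Both mitochondrial rRNAs also fell, mt-Rnr1 by 0.59 and mt-Rnr2 by 0.36 on the log2 scale. Reads of cytosolic rRNA from outside Gm42418 and CT010467.1, reads of another mammal assigned to Lars2 and an effect of 1-nitropyrene stay open, the last untested.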
